A study of Drosophila melanogaster with 4 samples.

How the data were processed

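H3K4me3 was measured by chromatin immunoprecipitation and sequencing in the S2-DRSC cell line, with 2 immunoprecipitated libraries and 2 input libraries, per the labels. The labels do not say whether the replicates came from separate cultures. Libraries were grouped by their titles into H3K4me3 immunoprecipitation and input. One deposited file was analysed, a list of peaks that names MACS as its source and FlyBase release 5 as its build, per the file headers. The submitters' processing notes name the build BDGP5, CASAVA 1.7.0.2, CASAVA 1.7.0.3, BWA and MACS2, without a role or order. The threshold of the peak calls, the input used and whether the replicates were pooled are not given in the sources used here. The list holds 1 score per peak as deposited by the authors, whose kind (a fold, a transformed p-value or another quantity) the file does not state. Scores ran from 5.96 to 846.25 and were used to describe, rank and filter peaks within this list and, in the closing section, to fit factors between sets of its peaks. Because the kind is open, a ratio of scores is a ratio on the authors' scale and not a ratio of histone marks.

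One peak started at position 0, so starts were taken as counted from 0, and positions are printed counted from 1. Width was the end minus the deposited start. The narrowest peaks were 200 bp wide (136 peaks) and the smallest gap between neighbours was 51 bp, so both are bounded by the peak caller. The lengths of the sequences were not given, so densities are per Mb between the first and the last peak. Read depth is unknown, and no value can be weighted by it.

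Peaks were counted per sequence with exact (Clopper-Pearson) 95% binomial intervals for shares and exact Poisson intervals for densities. Median scores and widths of X and 4 were compared with 2L, 2R, 3L and 3R, and placed among 10000 random peak sets of the same size. Intervals of unmatched ratios of medians came from 1000 bootstrap draws of runs of 10 neighbouring peaks. Sets matched on width were drawn within 10 deciles. For matched sets the intervals came from 10000 draws. In these X was resampled in runs of 10, but autosomal peaks were drawn singly within deciles. Peak positions were counted in 1 Mb bins, and gaps were compared with 1000 random placements within each arm. A strong peak was one with a score of at least 100 and a wide peak one over 2000 bp. Peaks named are the 10 highest by score and the 10 widest of the list, the highest and the widest of 2L, 2R, 3L, 3R, X and 4, and the 3 longest peak-free stretches; the text prints those that lead. These rules, comparisons, bins and alternatives were fixed before the data were examined, except for the score of at least 100, the 200 kb limit for peak-free stretches, the 500 bp limit for close neighbours, the intervals from runs of peaks, the percentile ratios, the comparisons by width class, the score medians of bins, those by single autosomal arms (with sets drawn from the 4 autosomal arms alone), the score segments described in the closing section, and the alternatives named there as added, which were chosen after seeing the data. Further exceptions were densities over the span between first and last peak, since densities were planned only with given sequence lengths. The comparison of chromosome 4 with random sets and the ratio of variance to mean of bin counts were not in the plan either.

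Segments of like score were found on each arm by splitting the ordered ranks of the scores at the point of largest difference, with at least 25 peaks on each side, where at most a share of 0.01 of 999 random orders gave as large a difference. The methods were tested on simulated data. A step of 0.5 in scores over the 1370 peaks of 3L was found within 30 peaks of its place in 95.0% of 20 lists. A test of whether 1 factor turns one set of scores into another kept a true factor in 100% of 20 lists of independent scores, so it was not tested on simulated scores that are correlated along the arm. On such lists the interval for the level of strong peaks held 1 in 95.0% where only their number fell, and lay below 1 in 95.0% where all scores were scaled by 0.5. The interval for the ratio of upper scores after 1 factor held 1 in 90.0% where all scores were scaled by 0.5. It excluded 1 in 95.0% where strong peaks were fewer. Random sets of X size scaled by 0.9 fell below all unscaled sets in 15.0% of 20 lists, so differences of that size can go unseen by this comparison.

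The gene table used for names is of another release (6), so no gene was tied to a peak. The promoter share of peaks, the share of genes with a peak and the 23 gene lists fixed before the data were examined were therefore not run. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were the upper 5786 peaks by score, merging of peaks closer than 500 bp, bases in place of peaks, matched sets, all other sequences as the comparison, and bins of 500 kb and 2 Mb.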

Results

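The data described trimethylation of lysine 4 of histone H3 (H3K4me3), a mark found mainly at the starts of transcribed genes, in S2-DRSC cells. S2-DRSC is a male cell line of Drosophila melanogaster that was derived from late embryos and is widely used for cell culture experiments. Chromatin was crosslinked with 1.8% formaldehyde for 15 min, and 2 libraries from immunoprecipitation with an H3K4me3 antibody and 2 input DNA libraries were made. The values analysed here were 1 list of peaks called by the authors. It held 11572 peaks on 14 sequences of FlyBase release 5, each with a start, an end and a score. The list carried no value for a single library, so no spread between replicates could be given for any value. Read depth was unknown. Intervals below cover counting error or the sampling of peaks only, and peaks were not treated as replicates of the cells. The exact intervals of shares and densities take peaks as independent of each other.

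The first question was where in the genome the mark was found. Peaks lay on all large chromosome arms, and their density was highest on 2R among these. The arm 2R carried 1516 peaks, or 71.7 per Mb of the span between its first and last peak (95% exact Poisson interval 68.1 to 75.4). The arm 3R carried 1693 peaks (60.7 per Mb), 2L 1353 (58.8 per Mb) and 3L 1370 (56.1 per Mb). The X chromosome carried 1171 peaks, or 52.2 per Mb (49.3 to 55.3), and the small chromosome 4 carried 62, or 49.3 per Mb (37.8 to 63.2). X held 16.5% of the peaks of X and the 4 large autosomal arms (95% Clopper-Pearson interval 15.6 to 17.4). Among the upper 5786 peaks of the list by score that share was 7.42%. After peaks closer than 500 bp were merged it was 18.7%, outside the interval above. The exact intervals take peaks as independent, but the variance of peak counts in bins along the arms was 6.56 times their mean. The intervals are therefore too narrow, and they do not settle whether the density of X was lower than that of 3L or 2L.

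A large part of the list lay outside the assembled arms. The sequences named Het (heterochromatin), U and Uextra (sequence not placed on an arm) together held 4407 peaks, 38.1% of the list (37.2 to 39.0), but 21.2% of the bases in peaks. Uextra alone held 3580 peaks, or 124 per Mb. Its peaks were narrow, with a median width of 421 bp against 1015 bp on the 6 sequences 2L, 2R, 3L, 3R, X and 4, and 1 of them was wider than 2000 bp. Their median score was 39.0, but 893 of them reached a score of 100. The Het sequences held 289 peaks, 7 of them on YHet. Uextra holds short and repeated pieces of sequence, so the placement of reads there is less certain than on the arms.

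**Figure D1:**
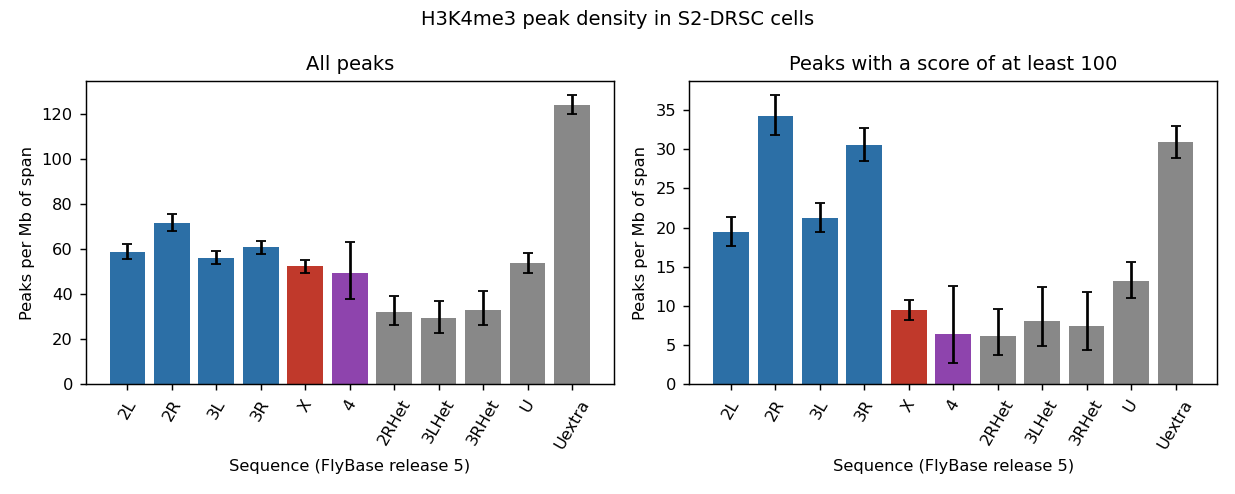
Peaks per Mb of span (vertical axis) on each sequence with at least 50 peaks (horizontal axis), for all peaks and for peaks with an authors' score of at least 100; bars start at 0 and whiskers are 95% exact Poisson intervals. X stood slightly below the autosomal arms for all peaks (52.2 per Mb). It stood far below them for peaks with a score of at least 100 (9.46 per Mb). The whiskers take peaks as independent and are therefore too narrow.

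The second question was how peaks of the X chromosome compared with those of the autosomes, since the line is male. X peaks had lower scores and were narrower. The median score was 30.3 on X and 84.0 on 2L, 2R, 3L and 3R combined, a ratio of 0.360 (95% bootstrap interval 0.326 to 0.387 over runs of 10 neighbouring peaks). The median width was 708 bp on X and 1088.5 bp on the autosomal arms, a ratio of 0.650 (0.614 to 0.683). Against all other sequences, which include the narrow peaks of Uextra, the width ratio was 0.989. None of 10000 random sets of 1171 peaks drawn from X and these arms had a median score or width as low, and the lowest set medians were 59.8 and 942 bp. These percentiles describe this list and are not tests across cells. Peaks with a score of at least 100 numbered 9.46 per Mb on X (8.23 to 10.8), against 19.4 on 2L (17.7 to 21.3), 21.3 on 3L, 30.6 on 3R and 34.3 on 2R.

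The gap in score between X and the autosomes was not the same along the distribution. The ratio of X to autosomal scores was 0.558 at the 25th percentile, 0.360 at the median, 0.413 at the 75th percentile and 0.769 at the 95th percentile. Against autosomal sets matched to X by width decile, the median score ratio was 0.642 (0.581 to 0.704). Against sets matched by score decile, a comparison added after seeing the data, the width ratio was 1.04 (0.971 to 1.11). Among peaks of up to 500 bp, which made up 28.5% of the peaks on X, the median score was 14.6 on X and 14.2 on the autosomal arms, so X was not lower there. Among peaks of 500 to 1000 bp the median score was 29.7 on X and 52.1 on the autosomal arms, and among peaks wider than 2000 bp it was 156 and 179. Restricted to the upper 5786 peaks of the list, the median score ratio was 1.03 and the width ratio 1.05. That restriction selects on the score itself. Chromosome 4 had a median score of 27.1 and a median width of 609.5 bp, ratios of 0.323 (0.246 to 0.479) and 0.560 (0.431 to 0.628) to the autosomal arms.

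**Figure D2:**
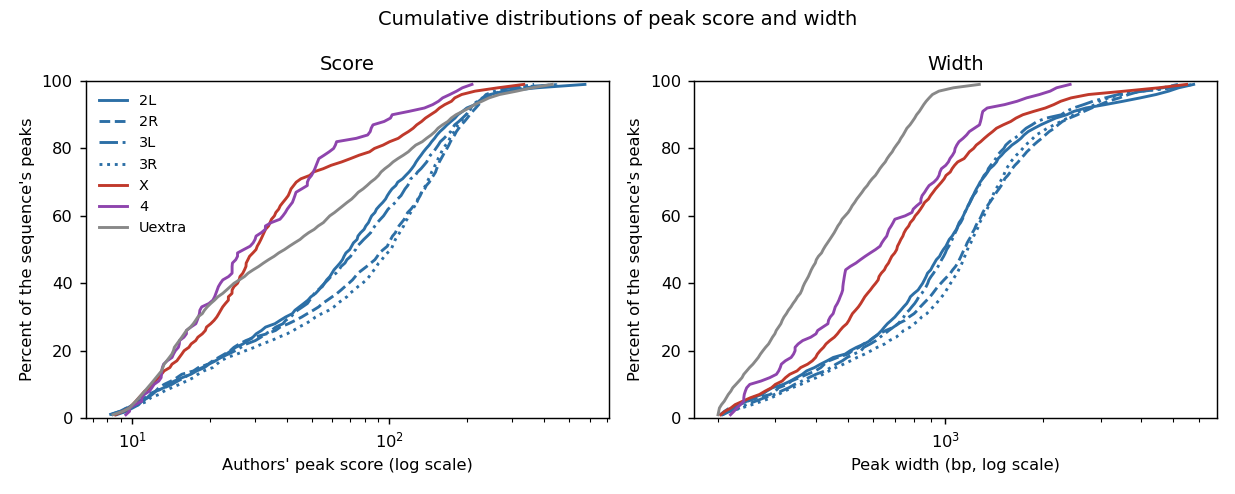
Cumulative distributions of the authors' peak score (left, log axis) and of peak width in bp (right, log axis), as percent of the peaks of each sequence, for 2L, 2R, 3L and 3R (blue), X (red), 4 (purple) and Uextra (grey). The curves of X and 4 lie to the left of the autosomal arms (median scores of 30.3 and 27.1 against 84.0), except at the lowest percentiles and, for the width of X, the highest. The width curve of Uextra lies farthest to the left (median 421 bp).

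The autosomal arms differed among themselves as well. The median score was 101 on 3R and 94.6 on 2R, ratios of 1.31 (1.16 to 1.41) and 1.16 (1.05 to 1.29) to the median of the other large autosomal arms. It was 73.9 on 3L and 70.1 on 2L, ratios of 0.843 (0.759 to 0.956) and 0.781 (0.705 to 0.860). Among 10000 random sets of each arm's size drawn from the 4 large autosomal arms alone, none had a median as high as 3R or 2R, and none as low as 3L or 2L. The sets draw single peaks and the intervals runs of 10, but score levels held over longer stretches. On 3R the median was 84.9 at 1686659–17848871 and 137 at 17849240–27905040. Set counts and intervals therefore overstate how surely whole arms differ, and the same limit holds for X. The share of peaks wider than 2000 bp was 16.6% on 2R (14.8 to 18.6), 14.9% on 3R, 12.6% on 2L, 11.3% on 3L and 8.11% on X (6.61 to 9.83).

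The third question was how broad the marked regions were. Over the whole list the median width was 714 bp, with quartiles of 389 and 1196 bp and a 95th percentile of 2679 bp, and 982 peaks (8.49%, 7.98 to 9.01) were wider than 2000 bp. On 2L, 2R, 3L, 3R, X and 4 alone the median was 1015 bp and 12.95% were wider than 2000 bp. The share wider than 2000 bp was 17.8% after peaks closer than 500 bp were merged. Among the upper 5786 peaks by score it was 16.5%, with a median width of 1151 bp. Wider peaks had higher scores, with a Spearman rho of 0.761 across all peaks and 0.832 across those of the 6 sequences, but 0.366 among the upper 5786 peaks by score. Peaks are not independent replicates, and the correlation describes this list.

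The widest peak spanned 9878 bp at X:21405506–21415383 and had a score of 553. It was followed by 3L:3408435–3417934 (9500 bp), X:4005543–4014607 (9065 bp) and 3R:25625376–25634428 (9053 bp). Of the 10 widest peaks, 5 lay on 3R, among them 3R:19871516–19879670 (8155 bp) and 3R:11444523–11452031 (7509 bp). The widest peak of 2R was 2R:3712984–3721120 (8137 bp), that of 2L was 2L:347851–355354 (7504 bp), and that of chromosome 4 was 4:1048825–1051529 (2705 bp). The peak with the highest score in the list, 846, lay at 3L:16638322–16641011 and was 2690 bp wide. The next was 2L:12434384–12437461, with a score of 785. The highest scores on the other arms were 705 at X:4178529–4183705, 696 at 3R:27238832–27244048, 654 at 2R:12427188–12432344 and 231 at 4:1318242–1319527. Of the 10 highest scores 3 lay on Uextra, and no peak was among both the 10 widest and the 10 highest. All positions are in FlyBase release 5, and the gene annotation of that release was not used here, so no gene is named for any peak.

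The last question was how the mark was spread along the arms. Every one of the 117 full 1 Mb bins of 2L, 2R, 3L, 3R and X held at least 1 peak, with a median of 59 peaks per bin. The emptiest bin held 9 peaks, at 14 to 15 Mb of 2L, and the fullest held 116, at 10 to 11 Mb of the same arm. The variance of the bin counts was 6.56 times their mean, where independent placement would give a ratio near 1. It was 3.81 after peaks closer than 500 bp were merged and 10.0 among the upper 5786 peaks by score. On the 6 sequences 45 stretches of over 200 kb had no peak. The longest were X:11915910–12475466 (560 kb), X:20395827–20901799 (506 kb) and 2L:14362852–14803916 (441 kb).

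Neighbouring peaks often lay close together. On X and the 4 large autosomal arms, 29.0% of the gaps between neighbouring peaks were shorter than 500 bp (27.9 to 30.0), against a mean of 3.22% and a highest value of 3.83% in 1000 random placements of the same peaks. The share was 30.8% on the autosomal arms (29.6 to 32.0) and 19.5% on X (17.3 to 21.9). Random placement gave 3.33% and 2.71%, so the excess was 9.25 times on the autosomal arms and 7.20 times on X. On Uextra the share was 8.49%, against 6.40% for random placement. Joining peaks closer than 500 bp left 9009 regions with a median width of 804 bp.

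The level of the scores also varied along the arms. Among full bins with at least 10 peaks, the highest median score was 165, at 25 to 26 Mb of 3R, and on X it was 87.8, at 1 to 2 Mb. The lowest bin median of each arm was 21.3 on 3L (23 to 24 Mb), 21.3 on 3R (9 to 10 Mb), 23.1 on X (11 to 12 Mb), 24.9 on 2L (22 to 23 Mb) and 31.5 on 2R (0 to 1 Mb).

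**Figure D3:**
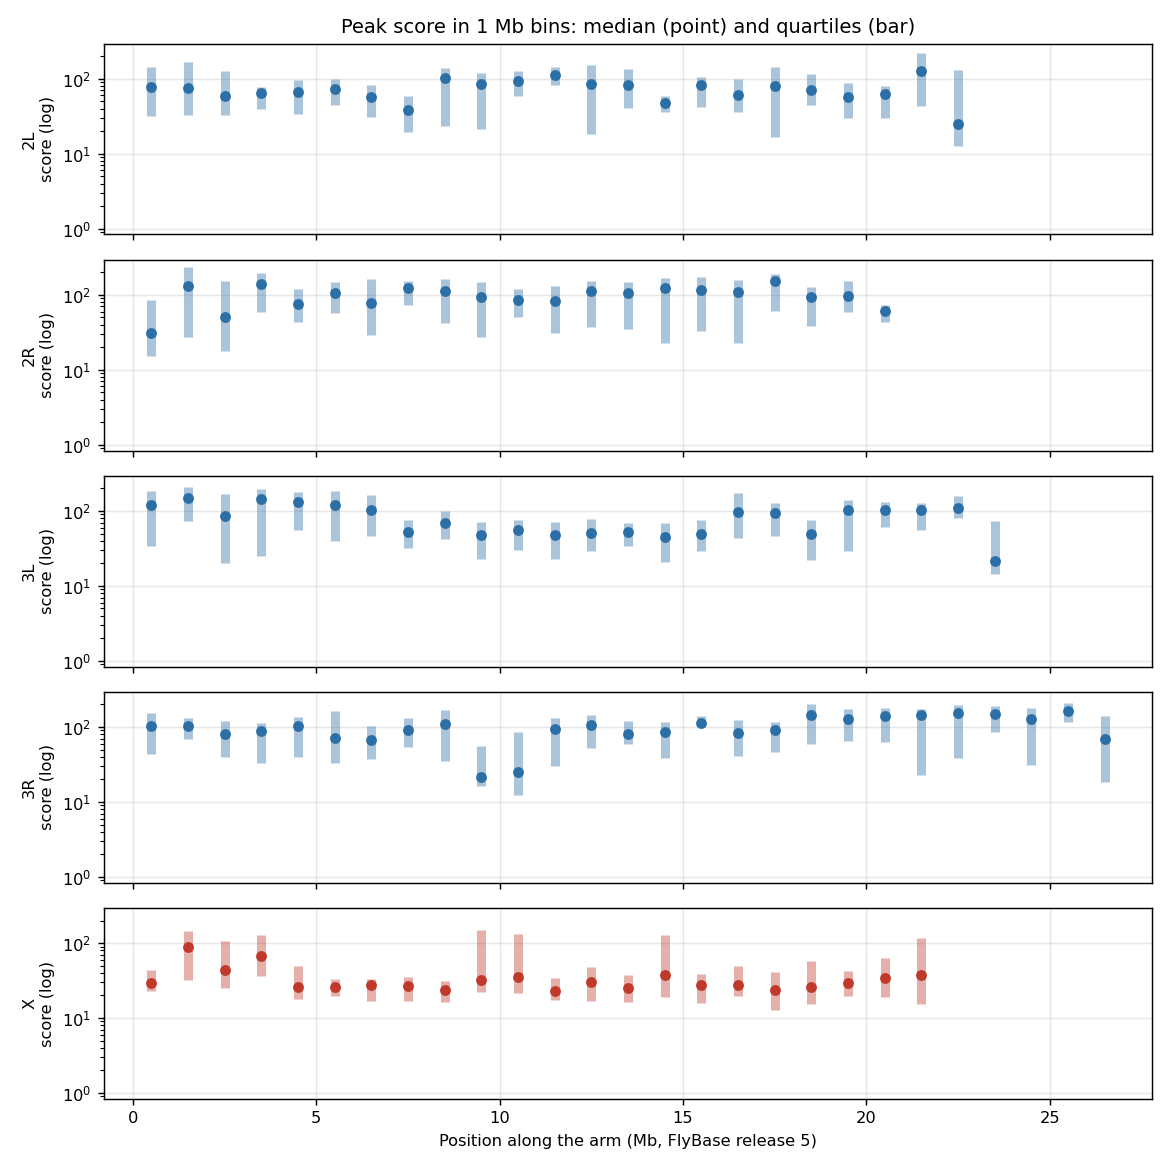
Median (points) and quartiles (bars) of the authors' peak score, on a log axis, in 1 Mb bins along 2L, 2R, 3L, 3R (blue) and X (red), with position in Mb of FlyBase release 5 on the horizontal axis. Most bins of X lie below those of the autosomal arms, and 3L and X change level along their length.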

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

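The score minimum of 10, main arms only, merging and matching for X width, merging for X score, and the alternatives for segments and resampling were chosen after seeing the data. The cause of each shift below was not tested, except that the restriction to the upper 5786 peaks selects on the score itself. Under it the X share was 7.42%, the Het, U and Uextra share 30.1%, the X to autosome score ratio 1.03 and width ratio 1.05 (both the other way from the whole list), the median width 1151 bp, the share wider than 2000 bp 16.5%, rho of width and score 0.366, the variance to mean ratio of bins 10.0 and the excess of close neighbours 11.1 times against 8.98. Merging peaks closer than 500 bp gave an X share of 18.7%, a Het, U and Uextra share of 43.4%, an X width ratio of 0.584, a median width of 804 bp, a wide share of 17.8%, rho 0.711 and a variance to mean ratio of 3.81. By bases the X share was 12.8% and the Het, U and Uextra share 21.2%. Matching on width gave an X score ratio of 0.642. Matching on score gave an X width ratio of 1.04 in place of 0.650, with an interval that holds 1 (0.971 to 1.11). Against all other sequences the X ratios were 0.473 for score and 0.989 for width. On the main arms alone the width was 1015 bp, the wide share 12.95% and rho 0.832. Of the remaining alternatives 30 were counted as keeping the result, 1 left 1 bin without a peak (upper 5786 peaks), and 3 turned an interval between blocks to exclude 1 when single peaks were resampled. Those counted as kept include 22 score segments in place of 28 and a resample share of 0.064 in place of 0.166 on X, both described below. No paired analysis was possible because the list holds no value per library, and leaving out a replicate was not run for the same reason. The planned filter on q was not run since the kind of score is not stated, and alternatives for promoters, genes and gene lists were not run without an annotation of the build. Unknown depth limits every comparison of weak peaks, since peaks under the authors' threshold are not in the list.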

Other observations

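The tests in this part were chosen after the results they bear on were seen, except the matching of X on width, which was planned. Scores were not spread evenly along the arms. Splitting each arm by score gave 28 segments, with 5 boundaries on 2R, 7 on 3L, 5 on X, 3 on 2L, 2 on 3R and 0 on 4. On 3L the peaks at 129472–6481556 had a median score of 126, those at 6481794–8715581 one of 65.1, those at 8884930–16400305 one of 50.02 and those at 19480769–23143560 one of 108. Peak density in these 4 segments ranged from 50.8 to 65.5 per Mb. In the other segments of 3L it ran from 39.1 per Mb at 23175729–24531600 (median score 25.6) to 85.5 per Mb at 16401604–16857961 (median score 159). On 3R the median was 84.9 at 1686659–17848871 and 137 at 17849240–27905040. On X it was 70.2 at 829323–4183705, 25.7 at 4211523–9213858, where 2.26% of the peaks reached a score of 100, and 118 at 9248455–10440659, where 54.0% did. The last 1.16 Mb of 2R, at 19985101–21146515, had a median of 60.3, against 160 in the 30 peaks just before it and 103 in the 1232 peaks at 2519138–19787234.

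The first pattern weighed was the low score of X peaks. It did not hold evenly along X or for X alone. The segments at 829323–4183705 and 9248455–10440659 had medians of 70.2 and 118, against 70.1 on 2L. The other segments of X had medians of 25.7 to 34.5. The small chromosome 4 had a median of 27.1, below the 30.3 of X. One multiplicative factor over the whole X is what a uniform change of scale would give. The distance it left between the distributions had a resample share of 0.001, the smallest the resamples can give. The resampling drew short runs of neighbouring peaks, but score levels held over longer stretches of the arms. That share is therefore likely too small, and it does not by itself exclude such a factor. Extra weak calls beside an autosomal density of strong peaks would leave that density unchanged, but it was 9.46 per Mb on X against 19.4 on 2L. Narrower peaks alone would give a ratio of 1 after matching on width, and it was 0.642. The kind of score is unknown and need not follow read number in proportion, so a lower DNA dose of X in male cells, or differences in the mark itself, may still contribute; neither was tested, since no read depth was analysed here.

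The second pattern was the blocks of like score. The real order of the peaks gave 22 boundaries, and 100 random orders gave at most 2. Since scores of neighbours correlate (rho 0.231 for adjacent peaks and 0.091 for peaks 10 apart), runs of 10 neighbours were also shuffled whole, and 0 of 100 such orders gave as many boundaries, with at most 7. Correlation over longer runs was not excluded in this way. At 50 peaks apart rho was 0.031, and 5 of 1000 random orders gave a value as high. Other settings gave 22 to 28 segments. A stricter share of 0.005 was used in a first exploration with fewer random orders, and with the full number of orders it gave 25 segments.

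The third pattern was the steps between neighbouring blocks, tested for all 6 pairs in which both blocks hold at least 100 peaks, a rule set after the blocks were seen. The edges of the blocks were placed where these same scores differed most, and the resampling did not place them anew. The shares and intervals below do not allow for that choice. One factor between the blocks is what a change in DNA copy number might give if scores followed copy number in proportion. The share of resamples that reached its distance between the distributions was 0.009 for the first pair of 3L. It was 0.008 for the first pair of 3R and 0.007 for the step of 3R at 17849240. Each share was 0.018 after Benjamini-Hochberg adjustment over the 6 pairs, which argues against one factor over these whole blocks on the authors' scale. Both 3R pairs share a lower block that holds the low-scoring bins at 9 to 11 Mb (medians of 21.3 and 24.9). Whether one factor would hold on 3R without that stretch was not tested. One factor stays open between 6481794–8715581 and 8884930–16400305 of 3L (0.374). On X the distance did not reject it between 829323–4183705 and 4211523–9213858 (0.982) or between 10442715–18542072 and 18542227–22422924 (0.166). The distance covers only scores of at least 10.55, and the fitted factors of 0.211 and 0.285 would leave 32.2 and 24.5 such peaks per Mb. Peaks of any score numbered 53.0 and 50.9 per Mb, with lower Poisson bounds of 46.8 and 46.1. These densities argue against one factor on X unless the lower blocks had more peaks to scale than the higher blocks, which was not tested. Fewer strong peaks whose level is unchanged would keep the median score of peaks that reach 100, which fell to 0.803 (0.753 to 0.863) times that of the higher block at 17849240 of 3R, against the explanation, and was 1.01 (0.939 to 1.13) for the first pair of 3R, as it requires and where one factor would give 0.905. For the other pairs that ratio did not decide, at 0.891 (0.793 to 1.02) and 0.931 on 3L and, in the order above, 1.36 and 1.02 on X, the former resting on 6 strong peaks in the lower block.

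The resampling of these tests was changed from single peaks to runs of 10 neighbours, and the density comparison and the test of strong peaks were added, after results were seen. With single peaks the shares on X were 0.989 and 0.064, and the interval of 0.891 on 3L became 0.802 to 0.993, which excludes 1. The 90th percentile of the lower block was also divided by that of the scaled higher block, both taken only over scores of at least 10.55. That ratio excluded 1 for the first pair of 3L at 1.39 (1.10 to 1.602) and for the step at 17849240 of 3R at 1.15 (1.07 to 1.28). The latter pair includes the low-scoring stretch of 3R named above, for which the fitted factor does not allow. The ratio held 1 for the first pair of 3R at 1.22 (0.995 to 1.35), where the distance has the same limit, for the second pair of 3L at 0.867 (0.732 to 1.26), and on X at 0.953 (0.755 to 1.28) and 2.49 (0.932 to 2.69). With single peaks the intervals of 1.22 and 2.49 were 1.05 to 1.33 and 1.03 to 2.84. Leaving the densities above aside, the scores of the second X pair keep one factor open only under the wider resampling. No biological explanation was tested for any of the 3 patterns.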
